A study of Mus musculus with 56 samples.

How the data were processed

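The 56 samples were mouse microglia, the resident macrophages of the brain, measured in 3 ways. A droplet single-cell assay (10x) covered 8 libraries from cortex, with 2 libraries for each of wild-type mice at postnatal day 9 (P9), wild-type mice at day 28 (P28), and P9 mice labelled heterozygous (ST2 Het) or knockout (ST2 KO) for Il1rl1, the gene of ST2, the receptor of the cytokine IL-33. Bulk RNA sequencing covered 14 libraries of cultured microglia, 7 kept in medium and 7 given IL-33 at 200 ng/ml for 3 h. It also covered 16 libraries of microglia sorted from the cortex of Mapt-EGFP knock-in pups into Tau-GFP plus and Tau-GFP negative cells, 8 each, where GFP is made in neurons and its presence in a microglial cell is meant to mark uptake. The sample labels put these pups at day 10 and the design text at day 9. A further 18 bulk libraries (Smart-seq2) came from P9 cortical microglia sorted for high (10) or low (8) staining with TMRM, a dye that gathers in mitochondria with a membrane potential. The tissue was digested with papain and cleared on a Percoll gradient, and cells were selected with CD11b beads or by sorting. The protocol of the cultures also mentions a pretreatment with the inhibitor GSK-J4, and the sources used here do not say which cultures received it.

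Per the submitters' processing notes, the single-cell counts are UMI counts made with Cell Ranger on mm10, and the deposited matrix holds whole numbers for 27998 genes in 15507 barcodes. The deposited count table holds RSEM expected counts from Bowtie2 alignments to mm10, in which 25.3% of the values are not whole numbers. It lists 23420 genes, none of them mitochondrially encoded. Of its symbols, 27 were turned into dates by a spreadsheet and hold 0.134% of the counts. They stayed in the fits and are not named. The deposited TMRM values are FPKM, fragments per kilobase scaled to the mapped fragments, from TopHat2 2.0.10 and Cufflinks 2.0.2, so each gene's value is relative to the rest of its library and no read depth is known. Values with the Cufflinks status FAIL were set to missing, and loci with the same symbol were summed. The versions of Cell Ranger, Bowtie2 and RSEM and the gene annotations are not given in the sources used here. The file of TMRM high 8 ends early on chromosome X, so 504 symbols have no value in that library and its mean for such genes rests on the other 9. The count table has 35 columns, of which 30 match the sample labels and 5, which no label names, were not used. The barcode prefixes of the first wild-type P9 and P28 libraries carry no replicate number and were taken as replicate 1 because the prefixes of replicate 2 are numbered. Those of the first ST2 Het and KO libraries carry the number 1 and the word redo, which the sample labels do not use and which hints at shared handling of that pair.

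Barcodes with at least 500 genes and under 10% mitochondrial UMIs were kept, leaving 15335 cells. They were log-normalised and grouped from 2000 variable genes, 30 principal components and 15 neighbours by Leiden clustering at resolution 1 (scanpy 1.11.5, leidenalg 0.10.2, Python 3.11.15). Doublet calls by scrublet marked 49 cells and were not used. The 12 clusters were typed by fixed marker lists, and 9 of them, with 14348 cells, were microglia-like. Their UMIs were summed per library, since libraries and not cells are the replicates. Shares of cells in a state were computed after thinning each cell to 1000 UMIs (2000 as an alternative), with exact 95% Clopper-Pearson intervals, which cover counting error only.

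The summed counts of all 8 single-cell libraries went into 1 fit with a mean per group, from which P28 was compared with P9 and ST2 KO with ST2 Het, so that the 4 groups share 1 estimate of the spread. IL-33 was compared with medium, and Tau-GFP plus with negative, in separate fits of their own libraries, after the expected counts were rounded. These fits used the quasi-likelihood F test of edgeR 4.0.16 with TMM scaling and its default expression filter (R 4.3.3). The standard error (SE) given for these fits is the absolute log2 fold change divided by the square root of F. TMRM high was compared with low by limma 3.58.1 with an intensity trend on log2 of FPKM plus 1, for genes with a mean of at least 1 FPKM. The p-values, from tests in both directions, were adjusted by the Benjamini-Hochberg method within each comparison, and genes with an adjusted p under 0.05 are called higher or lower. Group values are means ± SD in CPM, counts scaled to a common library total after TMM scaling, or in FPKM. Fold changes of genes with no UMI in a group are lower bounds against a floor of 3 UMIs over that group. Bulk libraries of the count table held between 7709047 and 11826389 expected counts.

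The 35 gene lists, 21 for cell programmes and 14 for cell types, were tested by camera with its preset correlation of 0.01 and adjusted over the lists within a comparison. Counts of called members are over all genes, and where no second count is given the count adjusted over the list alone was the same. The test was repeated with a correlation estimated from each list, and calls that do not hold with it are named as such. A list was tested where at least 3 of its genes were measured, and fry was run beside camera with its values kept in the tables. The programme lists cover homeostatic microglia, the phagocytic postnatal or disease-associated state, phagocytic receptors and opsonins, lysosome, nuclear-encoded oxidative phosphorylation and the mitochondrially encoded respiratory chain. They also cover glycolysis, the tricarboxylic acid cycle, mitochondrial biogenesis and dynamics, ribosome biogenesis and Myc, cytosolic ribosomal proteins, the NF-kB inflammatory response, IL-33 receptor and PI3K-AKT signalling, the interferon response, the cell cycle, and immediate early and dissociation genes. The remaining programmes are the hypoxia response, cholesterol synthesis, cholesterol efflux and lipid handling, antigen presentation and the oxidative stress response. The cell types are microglia, border-associated macrophages (BAM), monocytes, neutrophils, T or NK cells, B cells, astrocytes, oligodendrocytes and their precursors, neurons, endothelial, mural and erythroid cells, and choroid plexus or ependymal cells. Signatures of up to 200 genes with an absolute log2 fold change of at least 1 were taken from each comparison and tested in the other 4, with adjustment over all 40 such tests.

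Named genes follow a rule. It takes the targeted genes (Il1rl1, Il1rap and Mapt), the 10 largest changes each way with a mean of at least 10 CPM or FPKM, and up to 4 members, by lowest p, of each list that was called or had at least 3 called members. Predicted genes were left out, and some genes that the rule takes are not reported here. The groups, comparisons, tests, lists, naming rule and all but 7 of the alternatives were chosen before the data were examined. Alternatives were DESeq2 1.42.0, limma with quality weights, other scalings, filters and pseudocounts, other sets of cells, a replicate block, and leaving out each library in turn. The labels do not say whether replicates of a group are separate animals or cultures, so the p-values measure only the spread between these samples. Nor do the labels say that a replicate number ties libraries of different groups together, so the fits are unpaired.

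Each fit was tested on simulated data in which 200 genes changed, 100 by 1 and 100 by 2 on the log2 scale. Of the former, 100 were recovered for P28 against P9, 98 for ST2, 98 for IL-33, 91 for Tau-GFP and 97 for TMRM. False calls made up 9.09%, 4.35%, 6.16%, 4.02% and 3.94% of all calls, so the first and the third came out above the intended 5%. The real P28 and Tau-GFP comparisons called far more genes than were changed here, 6195 of 11600 and 4570 of 12138. The simulated rates hold for the genes drawn and for few changes, and do not describe those comparisons. Recovery among weakly expressed genes was not examined separately. Gene positions are from GENCODE vM21 on mm10. The raw reads were not used here.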

Results

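Microglia clear material, sense damage and support synapses in the growing brain. Their expression was compared across 5 contrasts: IL-33 added to cultured cells, mice labelled knockout or heterozygous for the IL-33 receptor ST2, age, TMRM staining, and Tau-GFP signal.

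IL-33 is an alarmin, a cytokine set free by damaged or stressed cells, and it signals through ST2 and its partner chain to NF-kB. Cultured microglia given IL-33 (n = 7) had 456 higher and 383 lower genes than cells in medium (n = 7), of 10815 genes tested with edgeR, and 61 and 11 of these changed at least 2-fold. Sod2, the mitochondrial superoxide dismutase and an NF-kB target, rose from 291 ± 27 to 654 ± 30 CPM (mean ± SD), a log2 fold change of 1.17 ± 0.05 (SE, adjusted p = 1.8e-11). Saa3, an acute-phase protein, rose from 47.2 ± 11 to 195 ± 25 CPM (2.05 ± 0.12, adjusted p = 1.3e-09). Clec4e, a receptor for dead cells and mycobacterial lipid, rose from 125 ± 25 to 407 ± 39 CPM (1.71 ± 0.09, adjusted p = 6.6e-10). Each gene given here as higher lay above the medium median in 7 of 7 IL-33 libraries, and each given as lower in 0 of 7. On mm10, Sod2 lies on chromosome 17 from 13006846 to 13040063, Saa3 on chromosome 7 from 46711998 to 46715700, and Clec4e on chromosome 6 from 123281789 to 123289870.

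Ptges, which makes prostaglandin E2, rose from 96.6 ± 25.7 to 379 ± 28 CPM (1.98 ± 0.13, adjusted p = 4.0e-09). Irg1, which makes itaconate in mitochondria, rose from 118 ± 33 to 394 ± 49 CPM (1.73 ± 0.13, adjusted p = 3.5e-08). The neutrophil-attracting chemokine Cxcl2 rose by 1.86 ± 0.17 (adjusted p = 3.1e-07) and the cytokine gene Il1b by 1.81 ± 0.26 (adjusted p = 8.4e-05). The activation marker Cd69 rose by 1.93 ± 0.28 and the scavenger receptor Marco by 1.74 ± 0.21. Of 25 measured members of the NF-kB inflammatory list, 18 rose and none fell (21 and 1 adjusted over the list alone), with a median log2 fold change of 0.81. That list was called with the preset correlation (adjusted p = 1.9e-65) and with the estimated one (adjusted p = 1.4e-05). Its members Icam1, an adhesion molecule, Ccl3, a chemokine, and Nfkbia, the inhibitor that NF-kB induces, rose by 0.87 ± 0.06, 0.99 ± 0.07 and 0.65 ± 0.05. Socs3, a brake on cytokine signalling, rose by 1.40 ± 0.22 (adjusted p = 0.00023).

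Oxidative-stress genes rose as a list, with 7 of 18 members higher and none lower (12 and 0 adjusted over the list alone, median 0.22, adjusted p = 3.3e-09 preset and 0.00026 estimated). Slc7a11, the cystine importer that feeds glutathione synthesis, rose from 32.3 ± 2.4 to 77 ± 13 CPM (1.26 ± 0.09, adjusted p = 3.3e-08), and Fth1, the ferritin heavy chain, rose by 0.23 ± 0.04 (adjusted p = 0.00036). Of 23 glycolysis genes 13 rose and 1 fell (13 and 2 adjusted over the list alone), among them Pfkl, a step-limiting phosphofructokinase (0.35 ± 0.04, adjusted p = 1.0e-05). The glycolysis call (adjusted p = 2.0e-06) was lost with an estimated correlation (adjusted p = 0.0971), as was the hypoxia call, in which 5 of 12 members rose, Hif1a by 0.47 ± 0.05 (adjusted p = 0.0015 preset, 0.0568 estimated). The nuclear-encoded oxidative phosphorylation list was not called, with 1 of 75 members higher (0 adjusted over the list alone, adjusted p = 0.39).

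Genes of the resting state fell. P2ry12, the ADP receptor that steers microglial processes, fell from 15.1 ± 1.6 to 8.14 ± 2.2 CPM (-0.88 ± 0.15, adjusted p = 0.00037), and its relatives P2ry13 and Gpr34 fell by 1.10 and 0.95 on the log2 scale. Of 18 homeostatic genes 7 fell and none rose (10 and 1 adjusted over the list alone, median -0.14, adjusted p = 2.0e-06 preset and 0.0183 estimated). Gas6, a bridge between dying cells and their receptors, fell from 267 ± 25 to 159 ± 22 CPM (-0.75 ± 0.08, adjusted p = 1.1e-06). The lysosome list was lower, with 14 of 32 members down and 1 up (22 and 1 adjusted over the list alone, median -0.12, adjusted p = 2.1e-09 preset and 0.0156 estimated), including the protease gene Lgmn (-0.38 ± 0.05). Trem2, a lipid-sensing receptor, and Cd68, a lysosomal glycoprotein, fell by 0.24 and 0.20. They belong to the phagocytic-state list, in which 9 of 22 members fell and 1 rose (10 and 1 adjusted over the list alone, median -0.13, adjusted p = 2.0e-06 preset and 0.0324 estimated). The list of phagocytic receptors and opsonins was also lower, with 7 of 23 members down and 3 up (12 and 3 adjusted over the list alone, median -0.17, adjusted p = 0.00025 preset and 0.0308 estimated). In it the endocytic receptor Lrp1 fell by 0.29, while the complement gene C3 rose by 0.89 ± 0.10 (adjusted p = 5.0e-06).

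Il1rl1 was near the limit of detection in these cultures. It averaged 0.72 ± 0.52 CPM with IL-33 and 0.433 ± 0.32 CPM in medium, on 1 to 16 and 1 to 12 counts per library, and was too low to be tested, while Il1rap, the partner chain, averaged 13.1 ± 3.7 and 11.4 ± 2.3 CPM (0.20 ± 0.16, adjusted p = 0.59, higher in 5 of 7). Among cell types, the monocyte list was higher (2 of 7 members, 3 adjusted over the list alone, adjusted p = 0.00055 preset and 0.0166 estimated), as was the neutrophil list (1 of 5 members, Lcn2, 2 adjusted over the list alone, adjusted p = 0.0086 and 0.0430). The neutrophil call was lost with genes of at least 5 CPM alone (adjusted p = 0.296, range over alternatives 0.00061 to 0.296). Both lists hold genes that activated macrophages also make, such as Hp (1.50 ± 0.20) and Lcn2 (2.36 ± 0.32). Calls for ribosome biogenesis, ribosomal proteins, interferon, the cell cycle and the microglia list (adjusted p = 0.0281, 0.0016, 0.0396, 0.00046 and 0.0015) were lost with an estimated correlation (adjusted p = 0.298, 0.513, 0.513, 0.489 and 0.0971). The lists for the tricarboxylic acid cycle, mitochondrial biogenesis, IL-33 receptor and PI3K-AKT signalling and immediate early genes were not called (adjusted p = 0.333, 0.397, 0.342 and 0.103). Nor were those for cholesterol synthesis, cholesterol efflux, antigen presentation, border-associated macrophages, astrocytes, oligodendrocytes and endothelial cells (adjusted p = 0.39, 0.342, 0.109, 0.342, 0.971, 0.44 and 0.492). Neuron, mural and choroid plexus lists had too few measured genes, with means of 0.183, 0.336 and 0.143 CPM with IL-33 and 0.151, 0.259 and 0.15 CPM in medium, and the oligodendrocyte precursor list averaged 1.84 CPM with IL-33 and 2.58 CPM in medium.

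Cortical microglia of pups labelled ST2 KO at P9 were compared with those of ST2 Het littermates (2 libraries each, 639 and 776 against 1242 and 1235 microglia-like cells). In all, 36 genes were higher and 34 lower of 11600 tested, and 1126 had an unadjusted p under the threshold. Leaving out 1 library at a time, the counts ran from 13 to 111 higher and from 11 to 36 lower, and with no low-count filter they were 249 and 110. With the 4 libraries compared and their replicate number as a block they were 235 and 77, and whether the numbers pair these libraries is not known. Nfkbia was lower, at 78.4 ± 9.0 against 209 ± 17 CPM (log2 fold change -1.41 ± 0.08, adjusted p = 6.4e-06). Cxcl10, a chemokine driven by NF-kB and interferon, was lower at 3.25 ± 0.07 against 31.8 ± 3.2 CPM (-3.28 ± 0.28, adjusted p = 9.2e-05). Nfkbiz, an atypical inhibitor protein of the same pathway, was lower at 15.7 ± 4.2 against 45.2 ± 6.8 CPM (-1.51 ± 0.16, adjusted p = 0.0008), and the cytokine gene Tnf at 9.41 ± 0.24 against 18.8 ± 1.3 CPM (-0.995 ± 0.16, adjusted p = 0.0179). Each gene given as lower lay below the Het median in both KO libraries and each given as higher above it. On mm10, Nfkbia lies on chromosome 12 from 55489410 to 55492647 and Cxcl10 on chromosome 5 from 92346638 to 92348889.

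The targeted gene did not tell the 2 groups apart. Il1rl1, on chromosome 1 from 40429570 to 40465415, had 30 and 28 UMIs in the KO libraries and 36 and 46 in the Het libraries (6.77 ± 0.86 and 5.91 ± 0.86 CPM, log2 fold change 0.19 ± 0.35, adjusted p = 0.907). UMIs at the 3' end do not show whether an intact receptor can be made, so these values do not check the labels, and loss of ST2 is not shown. The sexes were also unevenly mixed: of microglia-like cells, 23.6% and 27.3% in the KO libraries had no UMI of Xist, the transcript of the inactive X chromosome, against 1.13% and 0.729% in the Het libraries. Eif2s3y, a gene of the Y chromosome, had 211 UMIs in KO and 0 in Het, at least 111-fold higher against a floor of 3 UMIs over the Het group.

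Of the gene lists, those of 3 responses had most of the lower members. Of 26 NF-kB list members 7 were lower and none higher (12 and 0 adjusted over the list alone, median -0.47), and the list was called with the preset (adjusted p = 1.8e-39) and the estimated correlation (adjusted p = 0.014). Among its members, Tnfaip3, which shuts NF-kB signalling off, changed by -0.97 ± 0.13 (adjusted p = 0.0047) and the chemokine gene Ccl4 by -0.82 ± 0.16 (adjusted p = 0.048). Of 25 interferon-response genes 3 were lower and none higher (12 and 1 adjusted over the list alone, median -0.62, adjusted p = 6.9e-20 preset and 0.014 estimated). They were the membrane restriction factor Ifitm3, at 13.3 ± 1.1 against 37.3 ± 4.4 CPM (-1.48 ± 0.15, adjusted p = 0.00049), and the antiviral genes Rsad2 (-2.10 ± 0.39, adjusted p = 0.0317) and Ifit3 (-3.89 ± 0.74, adjusted p = 0.0353), both under 10 CPM in each group. Without cells of clusters led by cell cycle genes Rsad2 was at 0.06, and the interferon call was lost (adjusted p = 0.123, range over alternatives 7.4e-29 to 0.123). Of 21 immediate early genes 8 were lower and none higher (14 and 0 adjusted over the list alone, median -0.39). That call (adjusted p = 4.1e-29) was lost with an estimated correlation (adjusted p = 0.0637). The transcription factor genes Jun and Junb changed by -0.67 ± 0.06 and -0.59 ± 0.08 (adjusted p = 0.00011 and 0.0047), and the phosphatase genes Dusp1 and Dusp2 by -0.72 ± 0.10 and -1.502 ± 0.21 (adjusted p = 0.0053 and 0.0047). Casp4, an inflammatory caspase, changed by -0.90 ± 0.15 (adjusted p = 0.0212) and the cathepsin gene Ctsh by -0.30 ± 0.06 (adjusted p = 0.0401).

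Among the higher genes, Pecam1, an adhesion molecule of endothelial and myeloid cells, was at 67.1 ± 3.1 against 36.2 ± 2.9 CPM (0.89 ± 0.09, adjusted p = 0.00038), and Acta2, a smooth muscle actin, rose by 1.20 ± 0.19 (adjusted p = 0.0169). The endothelial list mean over microglia-like cells was 13.6 CPM in KO and 8.23 CPM in Het, and the mural mean 3.31 and 1.47 CPM. Rpl6, Rpl15 and Rpl27, proteins of the large ribosomal subunit, rose by 0.54 ± 0.05, 0.64 ± 0.08 and 1.08 ± 0.19 (adjusted p = 0.00045, 0.0037 and 0.0254). They were the 3 of 40 ribosomal protein genes that passed (3 adjusted over the list alone, median 0.05, adjusted p = 0.0004), and the call was lost with an estimated correlation (adjusted p = 0.56). Nme2, a nucleoside kinase, rose by 1.07 ± 0.14 (adjusted p = 0.0039). Pcna, the sliding clamp of DNA replication, rose by 0.60 ± 0.11 (adjusted p = 0.0317) as the 1 of 32 cell cycle genes to pass (2 adjusted over the list alone, median 0.15, adjusted p = 5.3e-06 preset and 0.56 estimated).

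Further preset calls in the KO comparison did not hold with an estimated correlation. They were the homeostatic, lysosome, oxidative phosphorylation and mitochondrially encoded lists (preset adjusted p = 0.0302, 0.0074, 0.0235 and 0.0395, estimated 0.56, 0.573, 0.686 and 0.56). The others were cholesterol efflux, antigen presentation and endothelial cells (preset 0.0473, 0.0395 and 0.0119, estimated 0.484, 0.56 and 0.56), with the endothelial median at 0 and its mean at 0.06. Not called were the phagocytic state, phagocytic receptors, glycolysis, the tricarboxylic acid cycle, mitochondrial biogenesis and ribosome biogenesis (adjusted p = 0.514, 0.122, 0.97, 0.97, 0.971 and 0.9847). The IL-33 receptor and PI3K-AKT, hypoxia, cholesterol synthesis and oxidative stress lists were not called either (adjusted p = 0.9847, 0.705, 0.571 and 0.607). For the microglia, border-associated macrophage, monocyte, neutrophil, oligodendrocyte and neuron lists the adjusted p was 0.0812, 0.182, 0.814, 0.182, 0.359 and 0.0987, and the neutrophil median was 1.58, or 0.13 with groups at 0 set to their floor. The median and the mean of the phagocytic-state, glycolysis, tricarboxylic acid, mitochondrial biogenesis and IL-33 receptor lists differed in sign, all within 0.05 of 0.

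Between P9 and P28, cell cycle genes fell and homeostatic genes rose in cortical microglia. The microglia-like cells of the ages lay largely in different clusters, and the largest at P28 held 2632 and 2715 cells of those libraries against 8 and 6 of the P9 libraries. Of 11600 genes, 3173 were higher and 3022 lower at P28 (2 libraries each), 800 and 1035 of them at least 2-fold. Birc5, a regulator of chromosome segregation, fell from 166 ± 13 to 0.935 ± 0.01 CPM (-7.44 ± 0.15, adjusted p = 1.7e-12), and Top2a, the topoisomerase of dividing cells, fell from 129 ± 12 to 0.602 ± 0.29 CPM (-7.71 ± 0.24, adjusted p = 7.0e-11). Cst3, cystatin C, an inhibitor of cathepsins and an abundant microglial transcript, rose from 19288 ± 7 to 75234 ± 159 CPM (1.96 ± 0.03, adjusted p = 2.0e-13). Apoe, the lipid carrier, fell from 6921 ± 61 to 1182 ± 66 CPM (-2.55 ± 0.04, adjusted p = 6.9e-13). The direction was the same in both libraries of each group for each gene named. No list called in this comparison was called with an estimated correlation. On mm10, Birc5 lies on chromosome 11 from 117849251 to 117855743, Cst3 on chromosome 2 from 148871722 to 148875692 and Apoe on chromosome 7 from 19696109 to 19699188.

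All 32 cell cycle genes were lower at P28, also adjusted over the list alone, with a median of -5.35 (adjusted p = 6.8e-99), and the call was lost with an estimated correlation (adjusted p = 0.0609). After thinning to 1000 UMIs, 31.9% and 32.8% of P9 microglia-like cells held at least 3 UMIs of these genes, against 0.177% and 0.384% at P28 and 48.1% of the endothelial-led cluster. Clusters led by cell cycle genes held 1173 and 1082 cells of the P9 libraries and 1 and 1 of the P28 libraries. Stmn1, a microtubule regulator of dividing cells, fell from 799 ± 22 to 40.5 ± 6.2 CPM (-4.30 ± 0.10, adjusted p = 6.3e-12). Growth-linked lists were lower too. The ribosomal protein list had 35 of 40 members down (36 adjusted over the list alone, median -0.90, Rps19 at -1.33 ± 0.04). Ribosome biogenesis had 12 of 22 down (14 adjusted over the list alone, median -0.35), with the nucleolar protein gene Npm1 at -1.46 ± 0.05. Cholesterol synthesis had 18 of 20 down (19 adjusted over the list alone, median -1.14), with Sqle, which makes squalene epoxide, at -4.14 ± 0.21.

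Respiratory genes were lower at P28. Of 75 nuclear-encoded oxidative phosphorylation genes 66 fell and none rose (67 and 0 adjusted over the list alone, median -0.53), among them Cox4i1 of cytochrome c oxidase (-0.88 ± 0.05, adjusted p = 4.3e-09) and Atp5g3 of the ATP synthase (-1.17 ± 0.06, adjusted p = 3.7e-09). Of 13 mitochondrially encoded genes 10 fell (10 adjusted over the list alone, median -0.67), with mt-Co1 down from 4013 ± 26 to 1853 ± 41 CPM (-1.11 ± 0.04, adjusted p = 9.1e-11). Of 22 genes of the tricarboxylic acid cycle 18 fell (19 adjusted over the list alone, median -0.51), Idh2 by 0.93 ± 0.06. Preset adjusted p-values were 1.1e-11, 4.1e-05 and 0.0001, and all were lost with an estimated correlation (adjusted p = 0.18, 0.165 and 0.153). Oxidative stress genes had 8 of 16 members down and 2 up (9 and 3 adjusted over the list alone, median -0.42), the peroxiredoxin gene Prdx1 at -1.14 ± 0.05. That call was lost in 7 of 18 alternatives (adjusted p range 0.0017 to 0.119). The glycolysis and mitochondrial biogenesis lists were not called (adjusted p = 0.65 and 0.758).

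Homeostatic genes rose, 18 of 20 with none lower (18 and 0 adjusted over the list alone, median 0.43, adjusted p = 1.4e-10 preset and 0.0768 estimated). Selplg, a selectin ligand, rose from 1004 ± 9 to 3628 ± 45 CPM (1.85 ± 0.04), and Tgfbr1, a receptor of the TGF-beta signal that maintains microglia, rose by 1.75 ± 0.05. Tmem119, a microglial membrane marker, rose from 1257 ± 34 to 3062 ± 53 CPM (1.28 ± 0.04, adjusted p = 9.7e-11). The phagocytic-state list moved the other way, 13 of 23 members down and 6 up (13 and 6 adjusted over the list alone, median -0.46, adjusted p = 6.7e-06 preset and 0.071 estimated). Igf1, a growth factor for neurons and glia, fell from 36.9 ± 1.9 to 2.6 ± 0.07 CPM (-3.81 ± 0.15, adjusted p = 5.8e-10). Lpl, a lipase of lipid-laden macrophages, fell from 195 ± 5 to 32.5 ± 3.9 CPM (-2.58 ± 0.08), and the galectin gene Lgals1 fell by 2.95 ± 0.12. In the P9 cluster led by border-associated macrophage genes, which is not part of these sums, Lgals1 stood at 1153 and 1020.1 CPM against 65.7 and 69.8 CPM in microglia-like cells, and Igf1 at 414 and 329 against 34.6 and 36.7 CPM. That cluster made up 9.33% and 9.73% of cells at P9 and 1.84% and 1.71% at P28. Of 21 phagocytic receptors and opsonins 14 rose and 7 fell (14 and 7 adjusted over the list alone), with the engulfment receptor gene Mertk at 1.40 ± 0.06, the complement gene C1qa at 0.75 ± 0.03 and Gas6 at -1.67 ± 0.05. The median of that list was 0.44, its mean -0.01, and its call (adjusted p = 0.025) was lost with an estimated correlation (adjusted p = 0.171) and in 5 of 18 alternatives (range 0.00025 to 0.333). The lysosome list was not called (6 of 30 up, 14 down, 7 and 15 adjusted over the list alone, adjusted p = 0.458), with the cathepsin genes Ctss at 0.93 ± 0.04 and Ctsl at -1.15 ± 0.05.

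Among immune programmes, 15 of 25 interferon-response genes rose and 1 fell (median 0.79), Ifit1 by 2.26 ± 0.29, while Ifi27l2a, the exception, fell from 127 ± 2 to 29.6 ± 1.7 CPM. Antigen presentation had 10 of 14 members up and 1 down (median 0.71), including H2-DMa, which loads peptides on class II molecules (1.41 ± 0.07). Ddit4, a stress-induced brake on mTOR, rose from 9.58 ± 1.2 to 212 ± 14 CPM (4.47 ± 0.11, adjusted p = 1.5e-11), within a hypoxia list that had 6 of 11 members up (median 0.46). Upk1b, a membrane protein of epithelia, and Tgm2, a transglutaminase, rose by 5.19 ± 0.16 and 6.70 ± 0.34. Of IL-33 receptor and PI3K-AKT genes 12 of 27 rose and 3 fell (median 0.23), with the kinase subunit gene Pik3r1 at 1.34 ± 0.06. The NF-kB list was not called, with 10 of 26 members up and 10 down (11 and 10 adjusted over the list alone, adjusted p = 0.827): the chemokine gene Ccl5 rose by 5.996 ± 0.55, and Tnf and Cxcl10 fell by 2.19 and 3.25. Immediate early genes had 12 of 21 members down and 5 up (median -0.37), Fos at -1.49 ± 0.09. That list was not called in 7 of 18 alternatives, and without the clusters rich in such genes it leaned upward (adjusted p = 0.348, range over alternatives 1.2e-10 to 0.44). Cholesterol efflux and lipid genes had 8 of 14 down and 5 up (9 and 5 adjusted over the list alone, median -1.55), with the lipid-droplet gene Plin2 at -2.01 ± 0.08.

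For cell cycle, cholesterol synthesis, cholesterol efflux and hypoxia at P28 the estimated adjusted p was 0.0609. For ribosomal proteins, ribosome biogenesis, oxidative stress, interferon, antigen presentation, IL-33 receptor and immediate early genes it was 0.133, 0.0942, 0.182, 0.171, 0.119, 0.0942 and 0.529. Their preset values were 6.5e-20, 0.0052, 0.0492, 0.0129, 9.6e-05, 0.0052 and 0.0495, and for cholesterol synthesis, efflux and hypoxia 2.8e-08, 6.6e-05 and 4.1e-05. Border-associated macrophage genes fell, 7 of 7 (median -2.89, adjusted p = 5.5e-09 preset and 0.0609 estimated), with Mrc1, the mannose receptor, down from 179 ± 5 to 11.4 ± 0.2 CPM and the chemokine gene Pf4 down by 2.89 ± 0.17. Neutrophil genes rose, 6 of 7 (median 5.82 also with zero groups at their floor, adjusted p = 0.01 preset and 0.171 estimated). S100a8 rose from 1.95 ± 1.2 to 136 ± 138 CPM, a value carried unevenly by the P28 libraries, and S100a9 rose by 5.82 ± 0.84. Ngp had 763 UMIs at P28 and 0 at P9, at least 346-fold higher against a floor of 3 UMIs over the P9 group. Among microglia-like clusters the neutrophil mean was highest, 70.5 CPM, in the cell-cycle-led cluster 7, which held 1 P28 cell, of P28 cortex 2. The largest P28 cluster stood at 25.8 CPM. The call held in all 18 alternatives. The neutrophil list averaged 27.8 CPM in 1 P28 library, 76.5 CPM in the other and at most 9.32 CPM in any P9 library. The P9 cells of cluster 7 are thus an unlikely source of its mean. Much of the uneven P28 value may rest on that cluster's 1 P28 cell, though the call held without cell-cycle-led clusters. Neutrophils or stray neutrophil RNA among the microglia-like cells were not tested for, so a rise within microglia is not shown. The microglia list rose in 10 of 12 members (median 0.39, adjusted p = 0.0018 and 0.171). Monocyte, oligodendrocyte, neuron and endothelial lists were not called (adjusted p = 0.895, 0.238, 0.678 and 0.721). The monocyte and endothelial medians and means differed in sign, and the astrocyte list mean was 18.7 CPM at P28 and 4.03 CPM at P9.

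**Figure D1:**
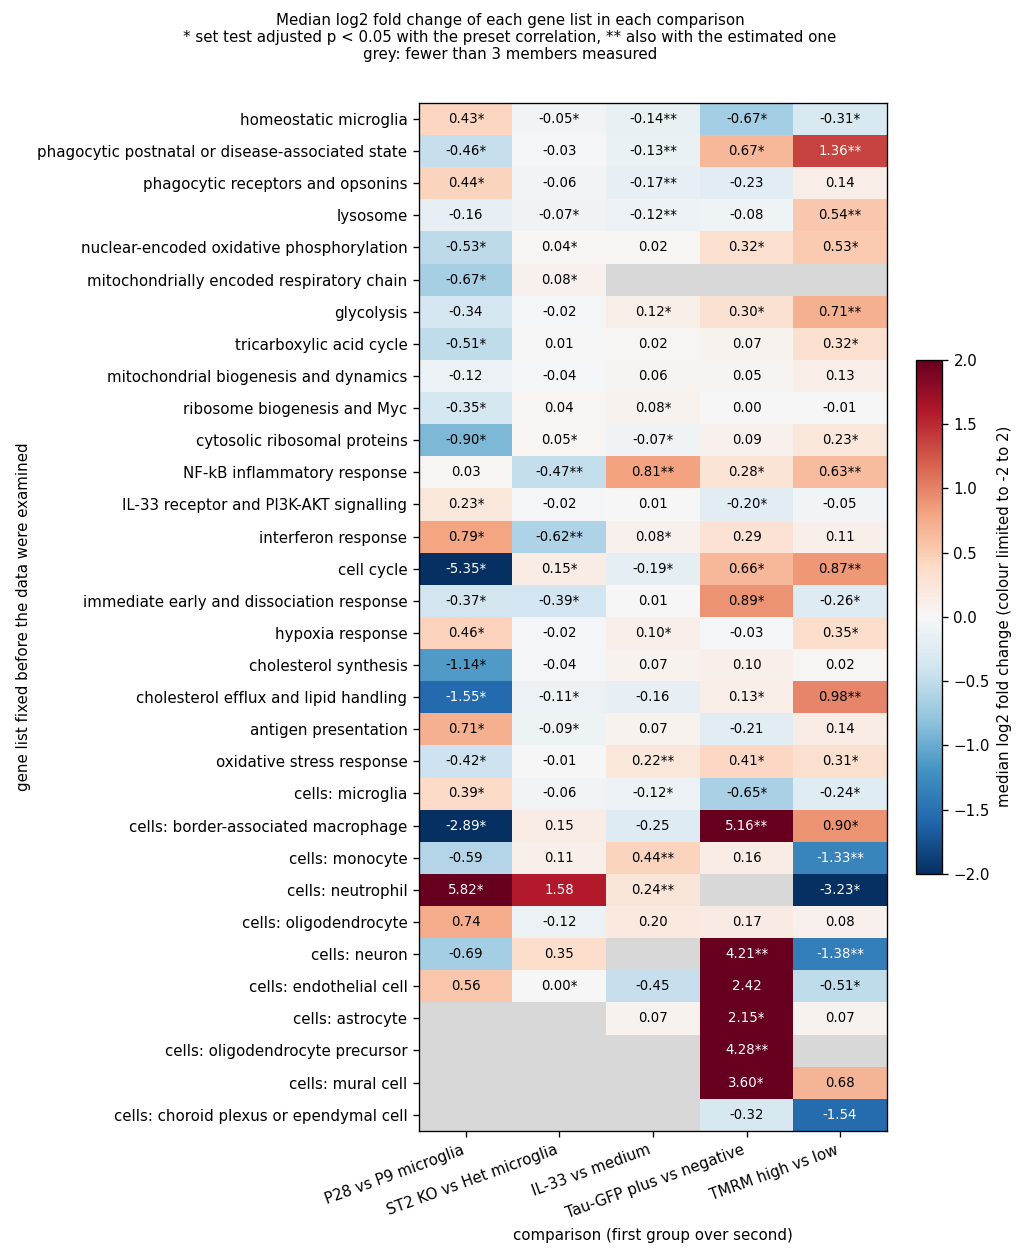
Median log2 fold change of each gene list (vertical) in each of the 5 comparisons (horizontal), with a star where the preset camera test had an adjusted p under 0.05 and a pair of stars where the estimated one did too. Phagocytic-state genes stand at 1.36 in TMRM high and 0.67 in Tau-GFP plus, and homeostatic genes at -0.31 and -0.67.

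TMRM is a dye that gathers in polarised mitochondria. Microglia with high TMRM (n = 10) had 2189 higher and 1054 lower genes than those with low TMRM (n = 8), of 10714 tested with limma, 202 and 85 of them at least 2-fold. The share of calls that were higher was 67.5%, and with upper-quartile scaling or quantile normalisation it was 44.8% or 50.9%, so the balance of directions depends on the scale. Upper-quartile scaling shifted the median of all genes by -0.10 on the log2 scale. Gpnmb, a glycoprotein of lipid-laden phagocytes, was at 95.8 ± 9.8 against 1.47 ± 1.1 FPKM (log2 fold change 5.38 ± 0.16, adjusted p = 5.3e-15). Spp1, osteopontin, was at 2153 ± 319 against 75.2 ± 33 FPKM (4.93 ± 0.20, adjusted p = 7.6e-13), and Igf1 at 96.9 ± 9.0 against 12.2 ± 1.6 FPKM (2.90 ± 0.08, adjusted p = 2.8e-15). Each higher gene named lay above the TMRM low median in 10 of 10 TMRM high libraries and each lower one in 0 of 10. On mm10, Gpnmb lies on chromosome 6 from 49036546 to 49070929, Spp1 on chromosome 5 from 104435118 to 104441050 and Igf1 on chromosome 10 from 87858265 to 87937042.

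All 23 measured phagocytic-state genes were higher, also adjusted over the list alone, with a median of 1.36 (adjusted p = 3.0e-30 preset and 0.00075 estimated). The integrin gene Itgax rose by 3.16 ± 0.15. Lysosomal genes were higher, 25 of 32 with none lower (26 and 2 adjusted over the list alone, median 0.54, adjusted p = 2.3e-15 and 0.0037). Ctsb, a cathepsin, rose from 992 ± 98 to 2374 ± 156 FPKM (1.26 ± 0.06), the tetraspanin gene Cd63 rose by 1.03 ± 0.06, and Atp6v0d2, a subunit of the proton pump, rose by 2.93 ± 0.17. Lipid-handling genes had 10 of 14 members up and none down (11 and 0 adjusted over the list alone, median 0.98, adjusted p = 9.3e-09 and 0.00088), with Apoe at 13716 ± 871 against 5456 ± 1316 FPKM (1.36 ± 0.09). The fatty-acid carrier gene Fabp5 and Plin2 rose by 2.72 ± 0.17 and 1.31 ± 0.07. The phagocytic receptor list, with 9 of 23 up and 2 down, was not called (adjusted p = 0.168).

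Energy genes were higher with TMRM. Of 75 oxidative phosphorylation genes 65 rose and none fell (69 and 0 adjusted over the list alone, median 0.53, adjusted p = 8.9e-17), and the call was lost with an estimated correlation (adjusted p = 0.155). Ndufb8 of complex I was at 249 ± 11 against 152 ± 22 FPKM (0.72 ± 0.07, adjusted p = 2.4e-07), and Sdha of complex II rose by 0.60 ± 0.07 (adjusted p = 3.4e-06). Glycolysis genes had 12 of 21 members up and none down (13 and 0 adjusted over the list alone, median 0.71, adjusted p = 2.7e-06 and 0.0364), including the lactate exporter gene Slc16a3 (1.46 ± 0.08) and lactate dehydrogenase Ldha, at 518 ± 53 against 237 ± 39 FPKM (1.14 ± 0.08). The tricarboxylic acid cycle had 13 of 22 up (17 adjusted over the list alone, median 0.32, adjusted p = 1.8e-05 and 0.0786). In the hypoxia list 5 of 13 rose, Bnip3, a mitophagy receptor, by 1.58 ± 0.14, and 1 fell (6 and 1 adjusted over the list alone, median 0.35, adjusted p = 0.0291 and 0.257). Cell cycle genes had 28 of 32 up (29 adjusted over the list alone, median 0.87, adjusted p = 9.5e-17 and 0.0101), with the cyclin gene Ccnb1 at 1.33 ± 0.08. Ribosomal protein genes had 21 of 40 up (25 adjusted over the list alone, median 0.23, Rpl19 at 0.34 ± 0.07), a call lost with an estimated correlation (adjusted p = 3.9e-05 and 0.486). It was also lost under quantile normalisation, where Rpl3 and Rpl4 were at -0.0041 and -0.0032 (adjusted p = 0.88, range over alternatives 1.3e-09 to 0.88). Oxidative stress genes had 9 of 15 up and 1 down (median 0.31, adjusted p = 0.0059 and 0.123), Prdx1 at 0.82 ± 0.10, and that call too was lost under quantile normalisation (adjusted p = 0.136, range 0.00043 to 0.136).

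NF-kB genes were also higher, 21 of 29 with none lower (23 and 0 adjusted over the list alone, median 0.63, adjusted p = 4.8e-13 and 0.0037). Cxcl2 was at 328 ± 37 against 37.8 ± 11.6 FPKM (3.13 ± 0.13), Tnf at 385 ± 38 against 94.3 ± 18 FPKM (2.03 ± 0.10), and Cxcl10 and Ccl5 rose by 2.65 ± 0.15 and 4.20 ± 0.34. Homeostatic genes were lower, 13 of 20 with none higher (13 and 1 adjusted over the list alone, median -0.31, adjusted p = 1.3e-09, lost with an estimated correlation at adjusted p = 0.051). Tmem119 was at 276 ± 22 against 567 ± 53 FPKM (-1.03 ± 0.06, adjusted p = 2.2e-10), P2ry12 fell by 0.65 and the fructose transporter gene Slc2a5 by 0.87. Immediate early genes had 10 of 21 down and 1 up (12 and 1 adjusted over the list alone, median -0.26, adjusted p = 4.4e-08 and 0.0786), with the transcription factor gene Klf2 at -1.22 ± 0.11 and the heat-shock gene Hspa1b at -1.25 ± 0.12. Not called were mitochondrial biogenesis, ribosome biogenesis, IL-33 receptor and PI3K-AKT, interferon, cholesterol synthesis and antigen presentation (adjusted p = 0.198, 0.535, 0.164, 0.24, 0.868 and 0.205). The ribosome biogenesis median and mean differed in sign, and the cholesterol synthesis test pointed down with a median and mean above 0. Il1rl1 averaged 1.38 ± 0.39 FPKM in TMRM high and 1.73 ± 0.56 in low.

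RNA of neutrophils, monocytes and neurons was higher in the TMRM low libraries. The neutrophil list averaged 140.3 ± 69 FPKM in low and 27.2 ± 26 FPKM in high, with 9 of 10 members lower in high (median -3.23, adjusted p = 3.3e-06 and 0.0786). S100a8 and S100a9, calcium-binding proteins of neutrophils, changed by -4.13 ± 0.95 and -4.24 ± 0.94, and Lcn2 by -3.41 ± 0.63. Monocyte genes had 4 of 6 lower (median -1.33, adjusted p = 0.00012 and 0.0267), with Plac8 at -2.12 ± 0.30. Neuronal genes had 3 of 3 lower (median -1.38, adjusted p = 0.00071 and 0.0454), with the noncoding RNA gene Meg3 at -3.04 ± 0.40. Ttr, the transthyretin of choroid plexus, averaged 5161 ± 11791 FPKM in low against 57.5 ± 27 in high, since most of it came from TMRM low 2 and 7. Border-associated macrophage genes were higher in TMRM high, 6 of 10 (8 adjusted over the list alone, median 0.90, adjusted p = 0.00034 and 0.0808), with the folate receptor gene Folr2 at 88.7 ± 7.4 against 10.2 ± 5.4 FPKM. The microglia list had 7 of 12 members lower (median -0.24, adjusted p = 2.7e-05 and 0.0704), and the endothelial list 2 of 5 lower (3 adjusted over the list alone, median -0.51, adjusted p = 0.042 and 0.333). Astrocyte, oligodendrocyte, mural and choroid plexus lists were not called (adjusted p = 0.882, 0.953, 0.457 and 0.0764), and the astrocyte median and mean differed in sign. The oligodendrocyte precursor mean was 0.114 FPKM in high and 0.119 in low, the erythroid mean 5.84 and 24.6 FPKM.

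**Figure D2:**
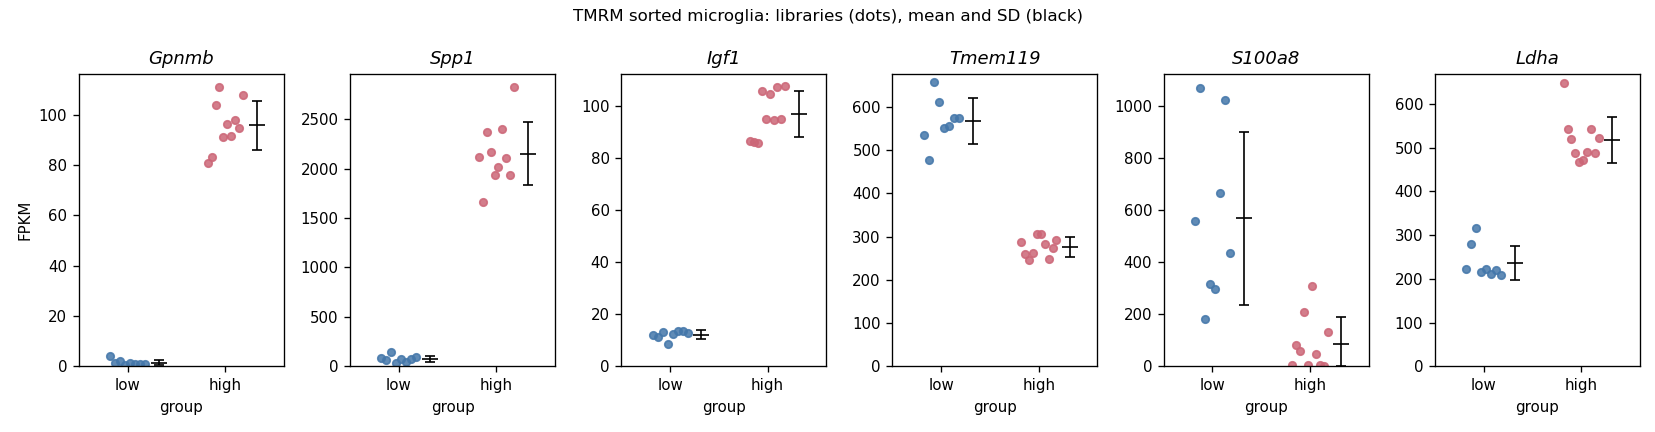
FPKM on a linear axis from 0 (vertical) of 6 genes in each TMRM high (n = 10) and TMRM low (n = 8) library. Bars give the mean ± SD, with the lower bar stopped at 0. Gpnmb stands at 95.8 against 1.47 FPKM without overlap, and Tmem119 at 276 against 567 FPKM.

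In Mapt-EGFP pups GFP is made by neurons, and microglia were sorted by whether they held it. Tau-GFP plus cells (n = 8) had 2516 higher and 2054 lower genes than negative cells (n = 8), of 12138 tested, with 1111 and 50 of them at least 2-fold. Lyve1, a hyaluronan receptor of macrophages along vessels, was at 458 ± 231 against 8.64 ± 4.7 CPM (log2 fold change 5.72 ± 0.43, adjusted p = 3.8e-08). F13a1, a transglutaminase of border macrophages, was at 818 ± 437 against 20.3 ± 10 CPM (5.33 ± 0.43, adjusted p = 6.8e-08), and Igf1 at 177 ± 41 against 34.3 ± 4.4 CPM (2.36 ± 0.13, adjusted p = 7.5e-10). P2ry12 was lower, at 4070.0 ± 718 against 7633 ± 472 CPM (-0.91 ± 0.09, adjusted p = 7.5e-07). Each gene named as higher lay above the negative median in 8 of 8 plus libraries, and each named as lower in 0 of 8. On mm10, Lyve1 lies on chromosome 7 from 110850607 to 110863239, F13a1 on chromosome 13 from 36867178 to 37050244 and P2ry12 on chromosome 3 from 59216272 to 59262871.

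All 10 border-associated macrophage genes were higher, also adjusted over the list alone (median 5.16, adjusted p = 6.0e-25 and 0.019), and their mean was 429 ± 160 against 56.9 ± 9.2 CPM. The haemoglobin scavenger gene Cd163 rose by 5.60 ± 0.47, the carbonyl reductase gene Cbr2 by 4.16 ± 0.22 and the membrane protein gene Ms4a7 by 4.75 ± 0.29. The scavenger receptor genes Cd36 and Msr1 rose by 5.32 ± 0.33 and 3.99 ± 0.29, the chemokine genes Ccl2 and Ccl7 by 3.57 ± 0.31 and 4.88 ± 0.49, and the matrix protease gene Mmp9 by 5.63 ± 0.61. Of 23 phagocytic-state genes 14 rose and 2 fell (14 and 2 adjusted over the list alone, median 0.67), and the call (adjusted p = 5.2e-08) was lost with an estimated correlation (adjusted p = 0.0893). Lgals1, Fabp5 and Apoe rose by 3.24 ± 0.20, 2.16 ± 0.22 and 1.02 ± 0.11, Apoe from 4138 ± 388 to 8410.5 ± 1864 CPM. In the P9 single-cell libraries, Igf1 stood at 414 and 329 CPM in the cluster led by border-associated macrophage genes and at 34.6 and 36.7 CPM in microglia-like cells. The list of phagocytic receptors had 9 of 25 members up and 12 down (median -0.23, mean 0.71, adjusted p = 0.797).

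Homeostatic genes fell, 20 of 20, also adjusted over the list alone (median -0.67, adjusted p = 1.2e-24, lost with an estimated correlation at adjusted p = 0.0505). Tmem119 fell from 2613 ± 219 to 1362 ± 234 CPM (-0.94 ± 0.09), Slc2a5 from 593 ± 57 to 289 ± 40 CPM (-1.04 ± 0.08), and Sall1, a transcription factor gene of microglial identity, by 0.76 ± 0.08 on the log2 scale. The microglia list fell in 12 of 12 members (median -0.65, adjusted p = 1.3e-16 and 0.0621). The lysosome list was not called (7 of 30 up, 10 down, adjusted p = 0.144), with Ctss at -0.63 ± 0.08. Immediate early genes had 13 of 22 up and 1 down (15 and 1 adjusted over the list alone, median 0.89, adjusted p = 2.4e-05 and 0.331), including the transcription factor genes Egr2 (2.45 ± 0.25) and Nr4a1 (2.36 ± 0.34). Oxidative phosphorylation genes had 61 of 75 up and none down (66 and 0 adjusted over the list alone, median 0.32, adjusted p = 1.5e-12 and 0.122), with Cox5b at 0.51 ± 0.06. Cell cycle genes had 23 of 32 up and 1 down (23 and 2 adjusted over the list alone, median 0.66, adjusted p = 3.2e-10 and 0.154), with Ube2c, which drives mitotic exit, at 1.12 ± 0.11. Oxidative stress genes had 9 of 16 up and 1 down (median 0.41, adjusted p = 0.0024 and 0.0646), with haem oxygenase Hmox1 at 1.86 ± 0.23.

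**Figure D3:**
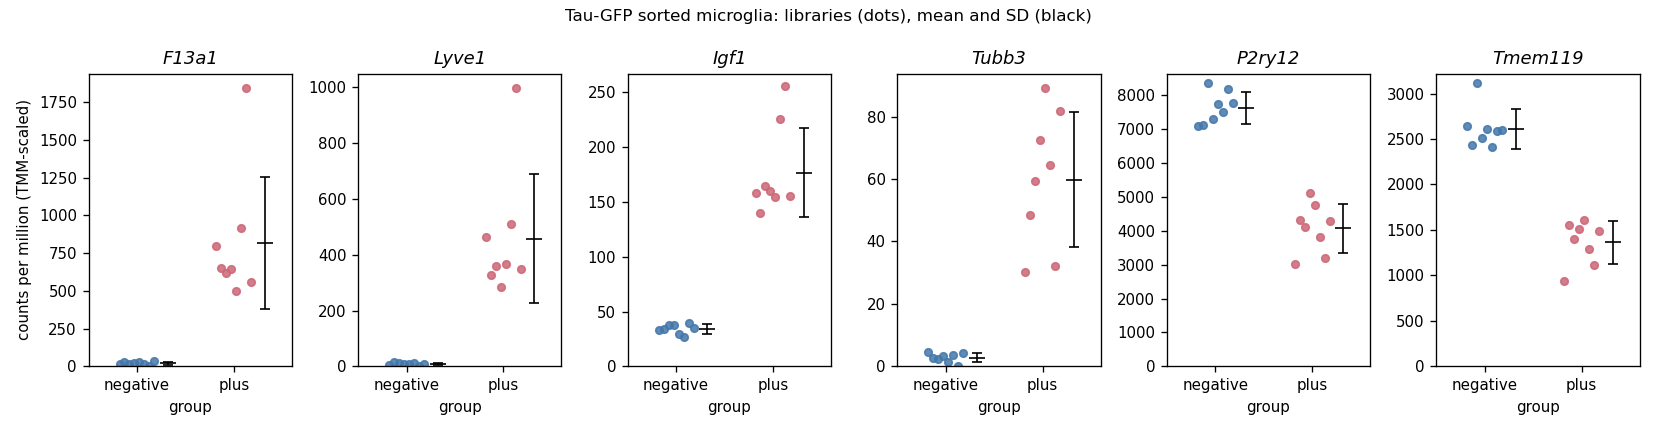
CPM on a linear axis from 0 (vertical) of 6 genes in each Tau-GFP plus and negative library (n = 8 each). Bars give the mean ± SD, with the lower bar stopped at 0. F13a1, Lyve1 and Tubb3 stand at 818, 458 and 59.8 CPM in plus against 20.3, 8.64 and 2.74 CPM, while P2ry12 and Tmem119 are lower in plus.

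Genes of neurons and other brain cells were higher in Tau-GFP plus as well. The neuron list rose in 9 of 9 members (median 4.21, adjusted p = 1.4e-11 and 0.019), and its mean was 19.4 ± 4.9 against 1.44 ± 0.68 CPM. Tubb3, a neuronal tubulin, was at 59.8 ± 21.7 against 2.74 ± 1.5 CPM (4.45 ± 0.39), and Dcx, a protein of migrating neurons, rose by 4.37 ± 0.40. Mapt, the gene of tau, on chromosome 11 from 104231390 to 104332090, averaged 0.516 ± 0.29 against 0.145 ± 0.08 CPM and was too low to be tested. Oligodendrocyte precursor genes rose in 3 of 3 members (median 4.28, adjusted p = 0.00052 and 0.0208), with the proteoglycan gene Cspg4 at 5.28 ± 0.58. Mural genes rose in 8 of 8 (median 3.601, adjusted p = 1.8e-07 and 0.0857), with the receptor genes Notch3 and Pdgfrb at 5.44 ± 0.48 and 4.96 ± 0.57. Astrocyte genes rose in 8 of 10 (9 adjusted over the list alone, median 2.15, adjusted p = 0.00014 and 0.166), with the gap-junction gene Gja1 at 2.75 ± 0.38. The endothelial list, with 6 of 10 up (9 adjusted over the list alone, median 2.42), was not called (adjusted p = 0.149), and its mean was 78 ± 130 CPM, mostly from Tau-GFP plus 3. The erythroid mean was 20.5 ± 26 against 0.637 ± 0.61 CPM.

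Other lists in the Tau-GFP comparison were called with the preset correlation alone. Glycolysis had 12 of 23 up and 4 down (15 and 4 adjusted over the list alone, adjusted p = 0.0366 and 0.166), the NF-kB list 11 of 26 up and 6 down (12 and 6 adjusted over the list alone, 0.0298 and 0.427), and cholesterol efflux 5 of 14 up and 1 down (0.00096 and 0.0893). The IL-33 receptor and PI3K-AKT list was lower, 11 of 27 down and 2 up (12 and 2 adjusted over the list alone, median -0.20, adjusted p = 0.0054 and 0.0893), while Il1rl1 itself averaged 13.5 ± 2.4 and 15.5 ± 4.1 CPM. Not called were the tricarboxylic acid cycle, mitochondrial biogenesis, ribosome biogenesis, ribosomal proteins, interferon, hypoxia, cholesterol synthesis and antigen presentation (adjusted p = 0.255, 0.447, 0.908, 0.125, 0.0835, 0.797, 0.411 and 0.0835). Monocyte, oligodendrocyte and choroid plexus lists were not called either (adjusted p = 0.411, 0.797 and 0.642), and the hypoxia and oligodendrocyte medians differed in sign from the mean or the test. The neutrophil mean was 22.1 ± 3.4 CPM in plus and 31.7 ± 1.7 in negative. T or NK cell and B cell lists had too few measured genes to be tested in the 5 comparisons, with means of 0.312 against 0.325 CPM and 9.48 against 11.6 CPM in Tau-GFP plus and negative. In TMRM high and low they were at 0.535 against 0.234 FPKM and 7.83 against 8.24 FPKM.

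Genes raised by IL-33 leaned lower in ST2 KO. Of 22 measured genes that IL-33 raised at least 2-fold, 2 were lower and none higher in ST2 KO (median -0.14, adjusted p = 0.00019 preset and 0.0442 estimated). That call was lost without the clusters rich in immediate early genes (adjusted p = 0.119, range over alternatives 0.00013 to 0.119). Of the 6 measured genes that fell at least 2-fold in KO, 2 rose with IL-33 (median 0.34, adjusted p = 8.7e-05 and 0.0084). Over all calls, 9 genes were lower in KO and higher with IL-33, where 1.18 would be shared if the calls were independent.

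Genes higher in TMRM high, in Tau-GFP plus and at P9 overlapped. Border-associated macrophage list means were higher on the same sides, at 429 against 56.9 CPM in Tau-GFP plus and negative. They were at 24.9 against 10.2 FPKM in TMRM high and low, and at 31.2 against 3.28 CPM at P9 and P28. Cell cycle genes were also higher on these sides. Whether macrophage RNA or dividing cells carry the overlap was not tested. Of 166 measured genes of the TMRM high signature, 123 were higher and 1 lower in Tau-GFP plus (median 0.85, adjusted p = 7.8e-35 and 0.00019), and of 162 measured in single cells 98 were lower and 23 higher at P28 (median -0.98, adjusted p = 1.3e-20 and 0.0015). Genes higher in Tau-GFP plus were also higher in TMRM high (64 of 109 up, 9 down, adjusted p = 1.9e-11 and 0.024) and lower at P28 (70 of 101 down, adjusted p = 6.8e-14 and 0.0161). Genes lower in Tau-GFP plus were lower in TMRM high (14 of 25, adjusted p = 0.0015 estimated) and higher at P28 (21 of 33, adjusted p = 0.0183 estimated). Genes that fell with age were higher in TMRM high (136 of 197, adjusted p = 0.0185 estimated) and in Tau-GFP plus (126 of 198, adjusted p = 0.0161 estimated), and genes that rose with age were lower in Tau-GFP plus (102 of 176, adjusted p = 0.0084 estimated). All genes counted, 946 were higher in both Tau-GFP plus and TMRM high against 370.2 if independent, and 528 lower in both against 191. Genes lower in KO were higher in TMRM high (4 of 8, adjusted p = 0.0269 estimated), and genes lower in TMRM high were higher with IL-33 (8 of 33, adjusted p = 0.0161 estimated). The signature of genes raised by IL-33 was not called in TMRM high (14 of 38 up, 12 down, adjusted p = 0.919). Over all calls, 164 genes were higher both with IL-33 and in TMRM high, against 85.3 if independent, and 147 were lower with IL-33 and higher in TMRM high, against 78.3. Signature calls lost with an estimated correlation were genes lowered by IL-33 at P28 (0.302), TMRM low genes at P28 (0.0742) and in Tau-GFP plus (0.149), and age-raised genes in TMRM high (0.122). Also lost were age-raised and age-lowered genes in ST2 KO (0.267 and 0.272) and age-lowered genes with IL-33 (0.272).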

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

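The tests on a lower share of microglia, on dilution in TMRM low, on phagocytic-state genes not raised in border-associated macrophages, and the runs on chosen cells or libraries were chosen after the results were seen. Bootstrap intervals of medians in this section resample the genes of a list, so they hold no spread between libraries.

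Within each bulk group, the highest or lowest library was compared with the spread of the rest for the genes and list means named, by Dixon's ratio of its gap to the whole range. Of 238 groups of values 37 held a library far from the others, and TMRM low 2 and Tau-GFP plus 5 held 7 and 6 of them. About 1 in 20 groups would do so by chance if values were independent and normally distributed. Many here are skewed or rise together, so the count does not measure an excess over chance. In TMRM low 2, Ttr stood at 33865 FPKM against 6262 in the next library, and the choroid plexus list mean at 3444, the erythroid at 183 and the astrocyte at 23.2 FPKM. Its endothelial and mural means were 16.7 and 8.74 FPKM, and its Sdha was the highest at 87.2 FPKM. TMRM low 3 had the highest Apoe (8620 FPKM) and Folr2 (22.2 FPKM) and the lowest P2ry12 (562 FPKM) of its group. TMRM low 1 had the highest Gpnmb (3.99 FPKM). TMRM high 6 stood apart in the neutrophil mean (88.8 FPKM) and Lcn2 (34.6 FPKM), TMRM high 3 in the erythroid mean (57 FPKM), and TMRM high 1 in Ldha (647 FPKM).

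Tau-GFP plus 5 was the highest of its group in F13a1 (1848 CPM), Lyve1 (999.7 CPM), Ccl2 (739 CPM), Nr4a1 (310.4 CPM), Lgals1 (128 CPM) and the border-associated macrophage mean (788 CPM, next 508 CPM). Tau-GFP plus 3 led in the endothelial mean (388 CPM, next 86.7 CPM) and the choroid plexus mean (27 CPM). Tau-GFP negative 6 had the highest microglia mean (6274 CPM), Ctss (5118 CPM) and Tmem119 (3111 CPM). Tau-GFP negative 4 led in the astrocyte mean (16.5 CPM) and Gja1 (14.8 CPM), Tau-GFP negative 1 in the mural mean (4.78 CPM), and Tau-GFP negative 8 had the lowest Apoe (3298 CPM). Among cultures, IL-33 1 was highest in Lrp1 (599.6 CPM), IL-33 3 in C3 (290.5 CPM), IL-33 7 in Fth1 (31834 CPM) and IL-33 2 in Mapt (0.923 CPM), while IL-33 2 was lowest in Saa3 (143 CPM). Medium 2 was highest in Clec4e (179.8 CPM) and medium 3 in Marco (26.2 CPM).

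NF-kB target, immediate early and interferon genes were lower in the libraries labelled ST2 KO. Male cells in the KO libraries were argued against as the source. With only cells that hold Xist and no Y-linked UMI, the median log2 fold change of the 72 members was -0.52, against -0.46 with all cells. Its 95% bootstrap interval over genes was -0.64 to -0.39. The Het libraries held more cells of 2 clusters with immediate early genes among their leading genes, 18.4% and 20.6% against 16.3% and 14.9% in KO. The smaller of them, with 103 cells, was led mainly by cell cycle genes. Without those clusters the median of the 51 NF-kB and interferon members was -0.38 (-0.60 to -0.25) against -0.60, an interval that spans the bound set for it, so a response to dissociation cannot be told apart from one to the receptor. Loss of ST2 signalling stays open beside it, as do mixed labels, which the 3' UMIs of Il1rl1 cannot check, and neither was tested.

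Genes of other cell types and of the phagocytic state were higher in Tau-GFP plus. A lower share of microglia that raises every other type alike was argued against. The mean of log2 of CPM plus 1 over the border-associated macrophage genes rose by 3.08 more than that over the endothelial genes (exact permutation p = 0.00295 over 12870 splits). The lists started from different levels in negative cells, with means of 56.9 and 18.6 CPM. On this scale a like change of share need not raise both alike, so the test decides nothing. A lower share of microglia in which such macrophages gain more than other cells would also give this result. A lower share thus stays open in either form. The microglia list mean was 3628 CPM in plus and 5465 CPM in negative. Border-associated macrophage RNA as the source of the phagocytic genes stays open. Of the risen members, 13 had their symbol in the single-cell matrix. Among these, 4 (Cst7, Gpnmb, Csf1 and Ctsb) were at or below the microglia-like level in those macrophages of both P9 libraries. The 11 list members not above that level had a median of 0.10 in Tau-GFP plus (-0.07 to 0.67) and went both ways, which decides nothing. Uptake of neuronal material by microglia stays open as the biological alternative and cannot be told apart from sorted macrophages here.

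Phagocytic-state genes were higher in TMRM high. Dilution of microglial RNA by other cells in TMRM low was argued against as the sole cause. It would lower homeostatic genes there as well, and their median was -0.31 (-0.52 to -0.15) in TMRM high. That median was known when the test was chosen. Some dilution, hidden by a fall of homeostatic genes in TMRM high, is not excluded, as neutrophil, monocyte and neuron RNA was higher in TMRM low. TMRM low 2, 3 and 7 as the source were argued against too, since without them the phagocytic median was 1.37 (1.04 to 2.06) against 1.36. That run does not remove other-cell RNA, as the lowest neuron mean of TMRM low, 0.8005 FPKM, lay above the highest of TMRM high, 0.388 FPKM. A state of phagocytic cells with polarised mitochondria may underlie the pattern, a hypothesis that was found on these data and not itself tested. Dye uptake that depends on cell size was not tested. A larger share of border-associated macrophages in TMRM high was not tested. Gpnmb, Cst7, Csf1 and Ctsb rose there. In both P9 libraries they were at or below the microglia-like level in those macrophages, Ctsb at 3870 and 3546 against 4252 and 3969 CPM. There Gpnmb and Cst7 each stood at 3.19 and 1.07 CPM and Csf1 at 2.13 and 6.45 CPM, all near the floor. At such levels a larger share would not by itself raise these genes, but values near the floor do not decide it. For members higher in those macrophages, such as Igf1 and Apoe, that share was not tested.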

How the results depend on the processing

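The runs limited to Xist-holding cells, without the clusters rich in immediate early genes, and without sets of Tau-GFP plus, TMRM low and TMRM high libraries were tests chosen after seeing the data.

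Called counts moved most in the ST2 comparison, 36 higher and 34 lower. They were 249 and 110 with no low-count filter, which tests more genes, 23 and 21 with all cells that pass the filters, 20 and 20 with all barcodes, and 23 and 12 without cell-cycle-led clusters, where 32 calls were shared. Without the clusters rich in immediate early genes they were 28 and 9, with 33 shared, and with Xist-holding cells alone 25 and 25, with 42 shared. With the 4 compared libraries alone they were 47 and 26, and with the replicate block in addition, which pairs these by number, 235 and 77, where all 70 were shared. Leaving out 1 library at a time gave 13 to 111 higher and 11 to 36 lower, with the lone library of a group assumed to vary like the others. The higher count was 60 without P9 cortex 1, 59 without P9 cortex 2, 21 without ST2 Het 1, 13 without ST2 Het 2, 13 without ST2 KO 1 and 111 without ST2 KO 2, and the lower count was 11 without ST2 Het 2 or ST2 KO 1.

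DESeq2 called 1940 genes higher at P28. With all 4 bulk groups in 1 fit, IL-33 calls were 184 and 154, in a fit that also brings in the spread of the sorted cells and tests 12748 genes. TMRM counts were 1427 and 1755 with upper-quartile scaling, which shifts the median of all genes by -0.10, and 1426 and 1376 with quantile normalisation. At a mean of at least 5 FPKM, where fewer genes are tested, 688 were lower. Leaving out 1 library at a time gave 2488 to 3298 higher and 2472 to 3105 lower at P28, 389 to 487 and 311 to 402 with IL-33, 2284 to 2601 and 1870.0 to 2121 in Tau-GFP plus, and 1988 to 2353 and 926 to 1218 in TMRM high. Without Tau-GFP plus 3, 5, 6 and 7, 1811 and 1380.0 genes were called, 2969 of them shared with all libraries. Without TMRM low 2, 3 and 7, 2373 and 1167 were called, 2801 shared, and without TMRM high 1 and 2 as well, 2768 and 1109. No low-count filter shifted the Tau-GFP median of all genes by 0.10.

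Some directions reversed, and the cause was not tested unless said. At P28, Plac8 and S100a4 were at 1.54 and 1.63 with all cells and at 1.55 and 1.5995 with all barcodes, which bring in the leukocyte cluster. The immediate early list turned upward at P28 without the clusters rich in them (adjusted p = 0.348, range over alternatives 1.2e-10 to 0.44). In ST2 KO without cell-cycle-led clusters, Il1rl1 was at -0.24, Rsad2 at 0.0616 and Kdr at 0.35. Leaving out 1 library at a time, Kdr ran from -0.34 to 0.15, the latter without ST2 Het 1, and it was at 0.015 without the clusters rich in immediate early genes. In TMRM high, Esam was at 0.16 with a pseudocount of 0.1, and under quantile normalisation Rpl4 and Rpl3 were at -0.0032 and -0.0041 and Ftl1 at -0.0339, all near 0.

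In ST2 KO the NF-kB list was called under every one of the 18 alternatives run. The interferon list was lost without cell-cycle-led clusters (adjusted p = 0.123, range over alternatives 7.4e-29 to 0.123), and the immediate early list without the clusters rich in such genes (0.106, range 1.8e-46 to 0.106). The cell cycle list was lost without cell-cycle-led clusters (0.852) and without ST2 KO 1 (0.708, range 3.2e-14 to 0.852), and the signature of IL-33 without the clusters rich in immediate early genes (0.119, range 0.00013 to 0.119). In all, 11 of 12 called lists of that comparison changed side in at least 1 alternative, against 3 of 15 with IL-33, 3 of 20 at P28, 2 of 16 in Tau-GFP and 4 of 19 in TMRM. Among named genes, 35 of 84 with IL-33, 7 of 117 at P28, 37 of 62 in ST2 KO, 19 of 119 in Tau-GFP and 15 of 109 in TMRM changed side somewhere. Of 88 shares of cells 73 moved when the cells were thinned to another depth or not thinned, as a deeper cell shows more genes.

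With the replicate number as a block, counts were 470.0 and 399 with IL-33, 2445 and 2092 in Tau-GFP, 1513 and 792 in TMRM, and 3217 and 3457 at P28. The residual correlation of libraries with the same number was over 0.1 in 2 of 7 pairs with IL-33, 5 of 8 in Tau-GFP and 2 of 8 in TMRM, where pairing was taken to need all. In Tau-GFP its median was 0.138 against -0.0142 for other numbers, and 8 of 16 libraries agreed best with their own number, a hint from the data that plus and negative cells of a number share a source.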

Other observations

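The tests on other splits of the samples were chosen after the results were seen.

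The IL-33, Tau-GFP and TMRM calls were set against 100 splits of the same libraries each. In the IL-33 comparison 1 of 100 splits, the real one, gave as many genes, 839 against at most 7 in any other drawn. A random grouping is thus an unlikely source of the count, provided that the libraries are independent, which the labels do not say. In the TMRM comparison 1 of 100 did, 3243 against at most 3. In the Tau-GFP comparison 1 of 100 did, 4570 against at most 2082, with the same proviso. The split with 2082 shared 7 of 8 libraries with the real grouping.

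Il1rl1 was far higher in microglia taken from tissue than in culture. It averaged 15.5 ± 4.1 CPM in Tau-GFP negative and 13.5 ± 2.4 CPM in Tau-GFP plus cells (n = 8 each) against 0.433 ± 0.32 CPM in cultured cells in medium (n = 7) of the same count table. The microglia list averaged 5465 CPM in Tau-GFP negative cells and 774 CPM in medium. Tissue, age and culture differ between these libraries, and no test was run between them.

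Wild-type P9 libraries held 9.33% and 9.73% cells of the cluster led by border-associated macrophage genes, the ST2 Het libraries of that age 2.25% and 1.41%, and the ST2 KO libraries 2.23% and 2.91%. P28 libraries held 1.84% and 1.71%. The sample labels carry a different date-like code for the wild-type than for the ST2 libraries. Genotype and collection therefore cannot be told apart in the difference between wild-type and ST2 libraries. The leukocyte cluster led by neutrophil genes made up 1.47% and 1.07% of P28 cells and 0.28% and 0.2% of P9 cells.

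The P9 and P28 libraries hold 11424 deposited barcodes, 11276 that pass the filters here and 10456 microglia-like cells, against 9391 cells in the design text. In Tau-GFP plus and negative alike, libraries 1 to 5 showed Xist and 6 to 8 Y-linked genes, so both groups hold both sexes in the same order. That order is a further hint that plus and negative cells of a number share a source. The unpaired fit, the permutation test and the splits of these libraries take no account of it. Cluster 10, with 232 cells, all of P28, had Cst7, Csf1, Ccl4, Cd83, Plaur and Ccl9 among its leading genes against all other cells. Cst7 and Csf1 belong to the phagocytic-state list, in which 13 of 23 members were lower and 6 higher at that age. The genes of this cluster were chosen after their values were seen.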
